A study of Glycine max with 12 samples.

How the data were processed

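Messenger RNA from roots of 2 nearly isogenic soybean lines was sequenced, with 3 libraries in each of 4 groups. TN09-16 is labelled susceptible and TN09-29 resistant to the soybean cyst nematode, and each line was either mock-treated or infected. Per the labels' protocols, seedlings aged 3 days received 3000 second-stage juveniles each or a mock of 0.1% agarose, and roots were collected 5 days later. Nothing in the labels shows that libraries of a group came from separate plants or cultures, so p-values measure the spread between these libraries, which may be technical. The parental lines that the protocols mention were not analysed here.

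Per the submitters' processing notes, the tools were FastQC 0.11.4, Trimmomatic 0.35, TopHat2 2.0.13, HTSeq and edgeR. The deposited values are whole-number counts per gene, not normalized, and the gene IDs in the files carry the name of the Wm82.a2.v1 annotation. The strand setting, the treatment of reads with several alignments and the versions of HTSeq and edgeR were not given in the sources used here. Each library listed 56044 genes and 5 entries that name no gene, and these entries were kept out of library sizes and tests. Of gene, ambiguous and no-feature counts together, ambiguous counts made up 10.1% to 21.1% and no-feature counts 2.39% to 3.75%. The entry for alignments that were not unique held 20766793 to 46816381 per library, or 5.56 to 14.1 per gene count. Values of genes with near-identical copies, of overlapping genes and of antisense genes are therefore uncertain.

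Counts on genes ranged from 2638280 to 6096416 per library, with a median of 3795849. Replicates of a group differed by a chi-square per degree of freedom of 3.63 to 26.5, so none agreed within sampling noise, and all 12 libraries were kept. Ratios of pooled counts have 95% intervals converted from exact Clopper-Pearson limits, and a group at 0 was given a floor of 3 counts over the group. PCR reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

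Tests used R 4.3.3 and edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups, which left 29470. Library sizes were scaled by TMM, and a quasi-likelihood model with a coefficient per group was fitted to all 12 libraries. The 5 contrasts were infection in each line, the difference between the infection responses, and the line difference in mock and in infected roots, with TN09-29 less TN09-16 in the last 3. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic, and intervals of listed genes used a t distribution with the residual degrees of freedom. CPM values are TMM-scaled. Principal components were taken from log2 CPM.

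The groups, contrasts, tests, first set of alternatives, gene lists and rule for named genes were fixed before the data were examined. Per comparison, the rule took the 8 higher and 8 lower genes with the largest log2 fold change among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups' libraries. For the difference of responses it took up to 6 per direction, without the condition on overlap. Tested members of the list for the rhg1 and Rhg4 loci and of the reference gene list were always included. The reference table used covers 59048 genes of the assembly Glycine_max_v4.0, and 0 of its entries matched a gene ID of the files. IDs and names are therefore not paired, and the values of at most 2 IDs per direction and comparison are printed. The identities of the listed genes come from general knowledge of the published loci, not from the files. Of 34 gene lists, 32 needed product names and could not be formed. Both remaining lists had 4 tested members, under the minimum of 5 set for the camera set test, so no set test was run.

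Chromosomes were read from the gene IDs. Genes past the threshold in both line comparisons in the same direction were tested per chromosome (Fisher's exact test, two-sided) and in windows of 100 consecutive tested genes with a step of 50 (one-sided for enrichment), each with Benjamini-Hochberg adjustment. The alternatives were RLE size factors, no filter on low counts, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, a replicate block, a fit of only the libraries compared, and leaving out each library in turn. Deviations from the group means correlated over 0.1 in all 3 same-number pairs of infected TN09-16 with infected TN09-29 (0.121, 0.261 and 0.153), so the numbers were taken to pair these libraries, although the labels do not say what a number shares. The spread between neighbouring genes was estimated with metafor 4.8.0.

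For the closing section, genes were called with 1 mock and 1 infected TN09-16 library left out, for each of 9 such pairs, and the median change in the left-out pair was set beside that in TN09-29. All libraries were thinned at random to the smallest total, 2638280. Unchanged groups were simulated 20 times against the shared TN09-16 mock libraries. Line differences averaged over treatments were scanned as running medians of 10 consecutive tested genes, against 1000 shuffles of gene positions. The number of calls was recounted in all 10 splits of 3 libraries against 3, and for the difference of responses in 100 drawn splits.

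The steps were tested on simulated counts drawn from the real means, library sizes and dispersions. In each simulation, 100 genes were changed by each of 2 fold sizes. Each gene had the same base mean and dispersion in all 4 groups. Near-equal shares recovered in the 2 lines were thus set by the simulation. Between real replicates, the chi-square per degree of freedom was 7.37 to 26.5 in infected TN09-29 and 4.84 to 12.2 in infected TN09-16. The shares therefore do not measure the power in the real TN09-29 libraries. For infection in TN09-16, over 28809 genes, 37% of genes changed 2-fold and 87% of genes changed 4-fold were recovered, beside 16 false calls. For infection in TN09-29, over 28797 genes, these shares were 33% and 87%, beside 5 false calls. For the difference of responses, over 28797 genes, they were 10% and 64%, beside 7 false calls. For the line difference they were 50% and 87% in mock roots, over 28842 genes and beside 10 false calls, and 39% and 86% in infected roots, over 28797 genes and beside 7 false calls. In simulated chromosomes, the 1 window found lay on the planted chromosome, and the planted run was found 0 genes from its start, reached by 1 of 100 shuffles.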

Results

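Gene expression in soybean roots was compared between a susceptible line, TN09-16, and a nearly isogenic resistant line, TN09-29, with and without the soybean cyst nematode, a parasite that feeds from cells inside the root. Each of the 4 combinations of line and treatment had 3 libraries, collected 5 days after inoculation. Counts on genes averaged 4610451 ± 1244382 (SD, n = 3) in mock and 4281287 ± 628715 in infected TN09-16, and 3271868 ± 471524 in mock and 4149540 ± 1769745 in infected TN09-29. The 5 most abundant gene IDs, all on chromosome 13, took 19.3% ± 3.01 and 21.3% ± 6.20 of the counts in mock and infected TN09-16, and 17.3% ± 3.98 and 22.5% ± 10.8 in mock and infected TN09-29. Their share reached 34.5% in TN09-29 infected replicate 2, the library with the fewest counts, and 28.3% in TN09-16 infected replicate 2. On the first principal component (20.4% of the variance), the TN09-16 mock libraries lay at -51.5 to -39.3 and the other 9 at -15.5 to 56.4. TN09-29 infected replicate 2 lay at -81.1 on the second component (17.3%), where the other 11 lay at -23.8 to 29.7.

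**Figure D1:**
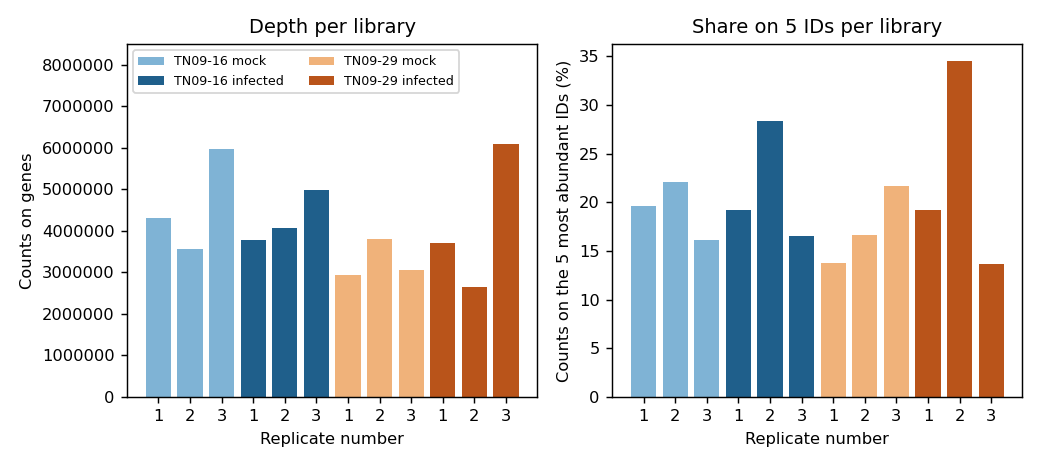
Counts on genes (left) and percent of those counts on the 5 most abundant gene IDs (right) for each of the 12 libraries, with 1 bar per library, coloured by group and numbered by replicate. TN09-29 infected replicate 2 has the fewest counts, 2638280, and the highest share, 34.5%.

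Infected and mock roots were first compared in the susceptible line. In TN09-16, 167 genes were higher and 191 lower in infected than in mock roots, with median log2 fold changes of 1.16 and -1.31. Glyma.13G084000 fell from 19.6 ± 8.46 to 0.0624 ± 0.108 CPM (SD, n = 3), with 253 counts in the mock libraries and 1 in the infected ones, a ratio of 231 (95% counting interval 41.1 to 9157). Glyma.06G109200 fell from 40.2 ± 18.8 to 0.525 ± 0.527 CPM, a log2 fold change of -6.30 (SE 0.57). Glyma.13G183500 rose from 0.0524 ± 0.0908 to 4.44 ± 3.85 CPM, with 63 counts against 1 and a ratio of 69.0 (11.9 to 2769), and Glyma.01G077000 rose from 0.351 ± 0.479 to 3.71 ± 2.40 CPM, a log2 fold change of 3.61 (SE 0.81). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 9.48e-06 and 9.05e-06 for the genes that fell and 0.00964 and 0.0303 for those that rose. In each of the 4 the libraries of the groups did not overlap, which the rule for named genes required. The 8 higher genes taken by the rule for named genes had fitted log2 fold changes of 2.64 to 5.53, and the 8 lower ones -3.30 to -7.48. The groups did not overlap in 18.8% of all genes, against 10% by chance. They did not in 357 of the 358 called genes either, but these were picked by their difference. The count was 145, 199 and 125 without mock replicate 1, 2 or 3, and 194, 300 and 117 without infected replicate 1, 2 or 3, and it was 1106 with no filter on low counts. Glyma.13G183500 was no longer called without mock replicate 1 or 3 or infected replicate 3, and Glyma.01G077000 without any of these or infected replicate 1.

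**Figure D2:**
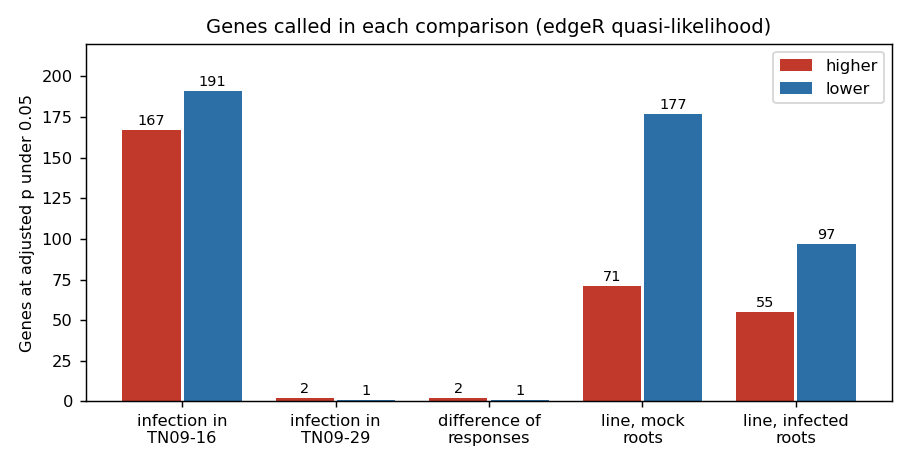
Number of genes past an adjusted p of 0.05 (vertical axis) in each of the 5 comparisons, with red bars for higher and blue bars for lower genes; line comparisons and the difference of responses are TN09-29 less TN09-16. Infection gave 167 higher and 191 lower genes in TN09-16 and 2 and 1 in TN09-29.

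In the resistant line, 2 genes were higher and 1 lower in infected than in mock roots. Glyma.07G014500 rose from 6.09 ± 4.28 to 72.4 ± 24.5 CPM (SD, n = 3), a log2 fold change of 3.65 (SE 0.37). Glyma.08G200200 rose from 31.2 ± 4.75 to 97.9 ± 48.6 CPM, a log2 fold change of 1.66 (SE 0.26), and Glyma.10G195700 fell from 13.7 ± 1.71 to 3.33 ± 0.709 CPM, a log2 fold change of -2.10 (SE 0.32). The adjusted p was 0.000117 for the first gene and 0.0236 for the others (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The libraries of the groups did not overlap in 10.8% of all genes, against 10% by chance. The 3 called genes are among these, but they were picked by their difference. At an unadjusted p under 0.05 there were 1960 genes, where 1473.5 are expected by chance. DESeq2 called 26 genes, and edgeR with no filter on low counts called 239. The count was 1 without mock replicate 1 or infected replicate 1 and 6 without infected replicate 2 or 3. Glyma.07G014500 stayed past the threshold in each alternative run, while Glyma.08G200200 did not without any 1 of the mock libraries or infected replicate 1 or in a fit of only the 6 libraries, and Glyma.10G195700 did not without any 1 of the mock libraries or infected replicate 1 or 3.

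Whether the lines responded differently to infection was tested directly, as the difference between the responses, and 3 genes passed. Glyma.06G109200 had 40.2 ± 18.8 and 0.525 ± 0.527 CPM (SD, n = 3) in mock and infected TN09-16, while its log2 fold change in TN09-29 was -0.91 (SE 0.44), a difference of 5.39 (SE 0.81). Glyma.16G017400 went from 201 ± 5.91 to 57.9 ± 11.8 CPM in TN09-16, while its log2 fold change in TN09-29 was 0.03 (SE 0.19), a difference of 1.83 (SE 0.27). Glyma.16G131200 went from 5.73 ± 0.781 to 23.1 ± 3.31 CPM in TN09-16, while its log2 fold change in TN09-29 was 0.09 (SE 0.20), a difference of -1.94 (SE 0.30). The adjusted p of each was 0.0243 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In mock and infected TN09-29, Glyma.06G109200 was at 11.02 and 6.58 CPM, Glyma.16G017400 at 67.5 and 69.7, and Glyma.16G131200 at 16.1 and 17.3. For Glyma.16G017400 and Glyma.16G131200, mock TN09-16 thus lay apart from the other groups. Glyma.06G109200 was highest in mock and lowest in infected TN09-16. The test cannot tell a differing response from a shift of the mock TN09-16 libraries, which stood apart on the first principal component. The test had low power, with 64% of simulated 4-fold differences recovered, and DESeq2 called 35 genes and edgeR with no filter on low counts 185. With edgeR, 0 genes passed without any 1 of the TN09-29 mock libraries or TN09-16 infected replicate 3. With all libraries, 1622 genes had an unadjusted p under 0.05, where 1473.5 are expected by chance. The count was 1 without TN09-16 mock replicate 1 or 3, 5 without TN09-16 infected replicate 2, 7 without TN09-29 infected replicate 3 and 68 without TN09-29 infected replicate 1. Besides the 4 libraries without which 0 genes passed, Glyma.06G109200 lost its call without TN09-16 infected replicate 1, Glyma.16G017400 without TN09-16 mock replicate 1 or 3, and Glyma.16G131200 without any of these or TN09-29 infected replicate 3.

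Genes called in TN09-16 mostly had a log2 fold change of the same sign in TN09-29, with smaller medians. Of the 167 higher genes, 84.4% had a positive log2 fold change in TN09-29, against 52.4% of all genes, and their median there was 0.41. Of the 191 lower genes, 80.1% had a negative one, against 47.6% of all genes, with a median of -0.34. The medians in TN09-16, 1.16 and -1.31, come from the comparison that selected these genes. Of 10000 random lists matched on mean expression, 0 had a median as far from 0 in TN09-29, for either list. The random lists drew genes independently, while called genes may change together, so this share is not a calibrated p-value. Across genes, which are not independent replicates, the responses correlated with a Pearson r of 0.269 and a Spearman rho of 0.244. The lines shared 1 higher call, where 0.0113 are expected of independent lists, and the 1 lower call in TN09-29 was not called in TN09-16. Pearson's r was 0.134 without TN09-29 infected replicate 1 and 0.0509 with no filter on low counts.

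**Figure D3:**
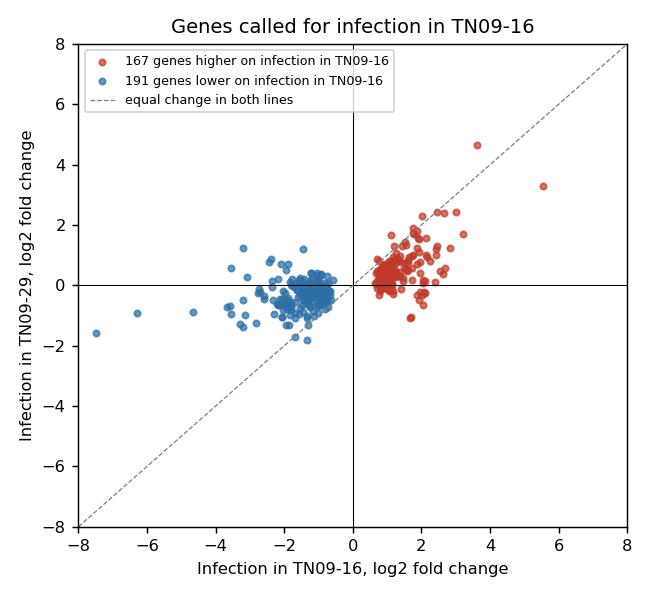
Log2 fold change on infection in TN09-16 (horizontal axis) and TN09-29 (vertical axis), with 1 point per gene called in TN09-16, red for the 167 higher and blue for the 191 lower genes, and a dashed line where both changes are equal. The median on the vertical axis is 0.41 for the red and -0.34 for the blue points.

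The lines also differed without the nematode. In mock roots, 71 genes were higher and 177 lower in TN09-29 than in TN09-16, with median log2 fold changes of 1.19 and -1.63, which stayed the same with 3 higher and 11 lower genes at 0 in a group set to their bounds. Glyma.17G173200 was at 45.8 ± 10.5 CPM in TN09-16 and 0.0830 ± 0.144 CPM in TN09-29 (SD, n = 3), with 629 counts against 1 and a ratio of 461 (95% counting interval 82.5 to 18250). Glyma.02G170800 had 122 counts in TN09-16 and 0 in TN09-29, at least 29.8-fold lower. Glyma.13G354300 and Glyma.20G038400 had 0 counts in TN09-16 and 57 and 56 in TN09-29, at least 25.9-fold and 25.5-fold higher. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 7.35e-10 and 4.58e-05 for the lower and 0.000276 and 0.000901 for the higher genes. Groups did not overlap in 16.4% of all genes, against 10% by chance. They did not in 244 of the 248 called genes either, but these were picked by their difference. The count was 100 and 118 without TN09-16 mock replicate 1 or 3, 104 and 109 without TN09-29 mock replicate 1 or 3, and 788 with no filter on low counts. The TN09-16 mock libraries that stood apart on the first principal component enter both this comparison and that of infection in TN09-16.

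In infected roots, 55 genes were higher and 97 lower in TN09-29 than in TN09-16, and Glyma.02G170800 and Glyma.13G354300 again had 0 counts in a line. Glyma.17G173200 had 633 counts in TN09-16 and 1 in TN09-29, a ratio of 621 (95% counting interval 111 to 24569), and Glyma.02G170800 had 105 and 0, at least 34.3-fold lower in TN09-29. Glyma.13G354300 and Glyma.09G211900 had 0 counts in TN09-16 and 44 and 32 in TN09-29, at least 14.9-fold and 10.9-fold higher. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 2.48e-10 and 6.27e-05 for the lower and 0.0027 and 0.0230 for the higher genes. Glyma.09G211900 was no longer called without TN09-16 infected replicate 2 or 3 or TN09-29 infected replicate 3, or without replicate 2 of both infected groups. The count was 258, 50 and 44 without TN09-16 infected replicate 1, 2 or 3, 98 without TN09-29 infected replicate 3, 65 in a fit of only the 6 infected libraries and 640 with no filter on low counts. The replicate numbers were taken to pair these libraries, a reading from correlations that the labels do not give. With the replicate number as a block over all 12 libraries, the mock ones included, the count was 240. A blocked fit of only the 6 infected libraries was not run.

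The line differences in mock and in infected roots shared 19 higher and 55 lower genes, where 0.133 and 0.583 are expected of independent lists, and 1 gene was called in opposite directions. Across genes the differences correlated with a Pearson r of 0.402 and a Spearman rho of 0.189, and r was 0.104 with no filter on low counts. Of the 74 shared genes, 73 lie on numbered chromosomes. Chromosome 17 held 10 of them, where 3.70 were expected, with an adjusted p of 0.0737 (Fisher's exact test with Benjamini-Hochberg adjustment over 20 chromosomes). By this test 0 chromosomes passed with the edgeR calls, and with DESeq2 calls chromosome 17 passed. With edgeR calls 2 had an unadjusted p under 0.05, chromosome 17 and chromosome 10. Chromosome 10 held fewer than expected, 0 called genes where 4.01 were expected. With edgeR calls, chromosome 17 also passed without any 1 of the libraries except TN09-16 infected replicate 2 and TN09-29 infected replicate 2. Of 557 windows of 100 tested genes, 2 overlapping ones passed, both on chromosome 17, and the one from Glyma.17G171300 to Glyma.17G198700 held 6 called genes against 0.249 expected. The number of windows was 5, 6 and 5 without TN09-16 infected replicate 1, 2 or 3 and 6 without TN09-29 infected replicate 3. Shared genes numbered 37 without TN09-16 infected replicate 2 or 3, 47 without TN09-16 mock replicate 1, 44 and 46 without TN09-29 mock replicate 1 or 3, and 43 without TN09-29 infected replicate 3.

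The rhg1 locus on chromosome 18 and the Rhg4 locus on chromosome 8 are known for resistance to this nematode, and their listed genes were followed in each comparison. The alpha-SNAP gene Glyma.18G022500, which encodes a protein of vesicle trafficking, was at 156 ± 5.41 CPM in mock TN09-16 and 159 ± 18.7 CPM in mock TN09-29 (SD, n = 3), a log2 difference of 0.03 (95% interval -0.32 to 0.37). The amino acid transporter gene Glyma.18G022400 differed by -0.38 (-0.81 to 0.05), the wound-inducible protein gene Glyma.18G022700 by 0.13 (-0.28 to 0.54) and the Rhg4 serine hydroxymethyltransferase gene Glyma.08G108900 by 0.37 (-0.08 to 0.81). Of the 5 listed genes, 4 were tested, and Glyma.18G022600 had too few counts, 73 over all libraries. In the 5 comparisons, 0 of the 4 passed edgeR's quasi-likelihood test over all genes, 0 passed adjusted over the list alone, 0 had an unadjusted p under 0.05, and 0 passed with DESeq2. The smallest p adjusted over the list alone was 0.145, in mock roots (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 4 reference genes, for actin, an ABC transporter, polyubiquitin and an elongation factor, had log2 fold changes of -0.10 to 0.18 over the 5 comparisons. Of these, 0 passed with edgeR, over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and 0 passed with DESeq2.

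**Figure D4:**
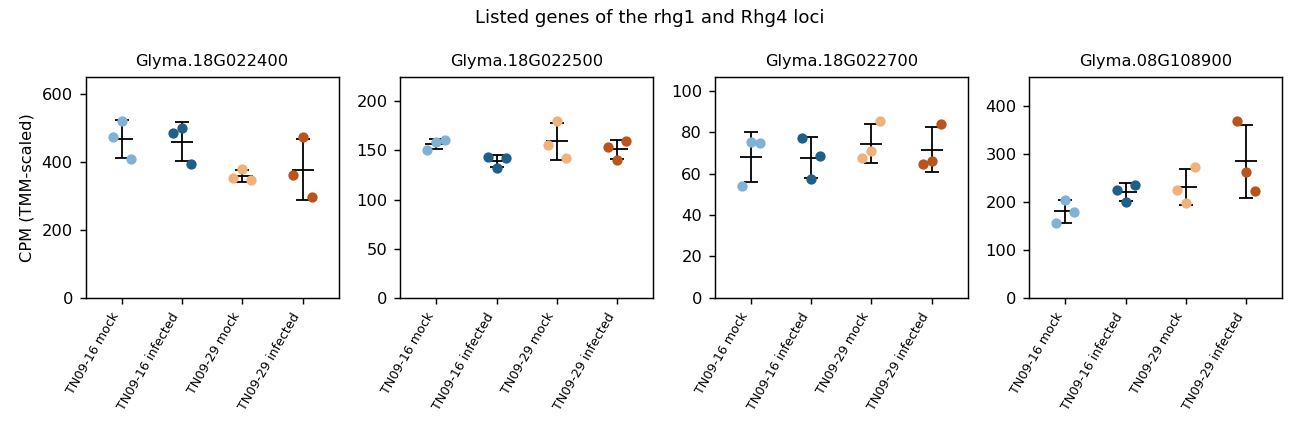
TMM-scaled CPM (vertical axis) of the 4 tested genes of the rhg1 and Rhg4 list in the 4 groups, with 1 coloured point per library and black bars for the mean and SD of 3 libraries. Glyma.18G022500 averages 156 CPM in mock TN09-16 and 159 CPM in mock TN09-29.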

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

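The sorting of the splits by the line whose labels were moved was chosen after their result was seen; the splits and the test of the difference were not. A difference between the lines in the response to infection singled out 3 genes. Glyma.06G109200 differed by 5.39 in log2 fold change, Glyma.16G017400 by 1.83 and Glyma.16G131200 by -1.94, each with an adjusted p of 0.0243 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A shift of the mock TN09-16 libraries could give such differences too, and this test cannot tell it from a differing response. Of 100 splits of the libraries into mock and infected within each line, the real one included, 9 gave 3 or more genes. The highest of the other splits gave 260 genes, many times the real count, and the high counts went with the TN09-16 labels. The 8 other splits with at least 3 genes left these labels in place and moved labels within TN09-29, and they were all of the drawn splits of that kind. They keep the infection difference of TN09-16 and so are not splits without an effect. The splits therefore cannot decide whether chance gives this number, and chance is not excluded. Of the 91 that moved TN09-16 labels, 0 gave as many.

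For the other comparisons, 3 libraries against 3 make 10 splits, too few for a share under 0.05. Infection in TN09-16 gave 358 genes and the highest other split 0, and infection in TN09-29 gave 3 and 0. The line difference gave 248 and 1 in mock roots and 152 and 7 in infected roots. In infected roots the replicate numbers were taken to pair the libraries. There the real split parts all 3 pairs, as do 3 others, which gave at most 7 genes. The 6 splits that part 1 pair gave 0.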

How the results depend on the processing

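Leaving out the infected library of each line with the highest share on the 5 most abundant IDs, taking that share as a term, and removing those IDs were alternatives chosen after seeing the data. In the order infection in TN09-16, infection in TN09-29, difference of responses, line difference in mock roots and in infected roots, no filter on low counts called 1106, 239, 185, 788 and 640 genes. The replicate block called 657, 35, 28, 388 and 240 genes and gave 6 windows. The block ended no call among the 18 results of genes printed for the 5 comparisons, and the averaged contrasts were not fitted with it. Outside the infected roots of both lines, the replicate numbers are not taken to pair the libraries, since 2, 0 and 0 of 3 same-number pairs correlated over 0.1 for infection in TN09-16, infection in TN09-29 and the line difference in mock roots. Of all 18 same-number pairs 8 did (range -0.162 to 0.261), and 9 of the 12 libraries correlated best with one of their own number, a hint from the data and not from the design. This reading by comparison was chosen after the counts were seen. A fit of only the 6 libraries compared called 682 genes for infection in TN09-16, 643 for the line difference in mock roots and 65 in infected roots. DESeq2 called 26 for infection in TN09-29 and 35 for the difference of responses and gave 4 windows, and the stricter filter called 5 for infection in TN09-29. With the share as a term the counts were 761 for infection in TN09-16, 10 in TN09-29, 12 for the difference of responses and 270 for the line difference in infected roots, with 5 windows. Without the high-share libraries they were 6 for infection in TN09-29, 5 for the difference of responses and 49 for the line difference in infected roots, with 5 windows. No filter gave 7 windows, and genes called in mock roots alone 6. Pearson's r of the infection responses was 0.0509 with no filter and 0.199 with the stricter one, and r of the line differences was 0.104, 0.319 and, without the high-share libraries, 0.360. Chromosome 17, with an adjusted p of 0.0737 in Fisher's exact test with all libraries, passed with DESeq2 (0.00234), with no filter (0.0114), with the share as a term (0.00384) and without the high-share libraries (0.0471). It also passed without each of 10 libraries, and not without TN09-16 infected replicate 2 (0.207) or TN09-29 infected replicate 2 (0.367), over a range of 0.0011 to 0.367. The cause of these shifts was not tested.

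Leaving out 1 library at a time gave 117 to 300 genes for infection in TN09-16, 1 to 6 in TN09-29, 0 to 68 for the difference of responses, and 100 to 236 and 44 to 258 for the line difference in mock and in infected roots. Windows ranged from 2 to 6, and r from 0.134 to 0.283 for the infection responses and from 0.338 to 0.416 for the line differences. RLE factors and removal of the 5 IDs kept each count of genes within 1.5 times. The 18 gene results printed for the comparisons kept their direction in all of 281 alternatives and lost the threshold in 40, and the 40 results of listed genes stayed short of it in all of 640. The set test camera, with a preset or an estimated correlation, and fry were not run, because no list had 5 tested members. Depth limits the counts: all libraries were thinned to 2638280 counts, which left 26752 genes tested. Then 224 genes were called for infection in TN09-16 and 1 for the difference of responses.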

Other observations

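The contrasts averaged over lines or treatments, the list of genes at 0 in a line, the tests on left-out libraries and on library measures, and those along the chromosomes other than the planned windows were chosen after the results were seen, and the tests without TN09-29 infected replicate 2 and at thinned depth before. Averaged over both lines, infection called 248 higher and 212 lower genes by edgeR's quasi-likelihood test, 236 of them also called in TN09-16 alone. Glyma.01G077000 rose by 4.14 on the log2 scale (SE 0.58), with 3.61 in TN09-16 and 4.67 in TN09-29, and Glyma.08G200000 by 3.78 (SE 0.71), with 3.76 in TN09-16 and 3.80 in TN09-29. Glyma.13G084000 fell by 4.52 on average on the log2 scale (SE 0.52), with -7.48 in TN09-16 and -1.57 in TN09-29, and Glyma.14G210600 fell by 2.29 (SE 0.30), with -3.30 and -1.28, and neither difference between the lines passed the test of the difference of responses. The 6 infected libraries did not overlap the 6 mock ones in 1.01% of all genes, where chance gives 0.216%. They did not in 131 of the 460 called genes either, but these were picked by their difference. Between the lines, 8 genes had 0 counts in all TN09-29 libraries and at least 5 in each TN09-16 library, and were at least 17.6-fold to 64.4-fold lower in TN09-29, while 0 tested genes met this in the other direction, which Glyma.13G354300 missed with 4 counts in 1 library of TN09-29.

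Infection called 358 genes in TN09-16 and 3 in TN09-29. Without TN09-29 infected replicate 2, 6 genes were called in TN09-29, where TN09-16 kept 117 to 300 without 1 of its infected libraries. This argues against the spread of that library as the whole source. The spread of the other TN09-29 infected libraries was not tested. The values also argue against depth, since TN09-16 had 224 calls with all libraries thinned to the smallest total. For genes called lower, the median fall in TN09-29 was 0.245 of the fall in TN09-16 pairs left out of the calling (0.221 to 0.333 over 9 pairs), which argues against an equal response hidden by low power. For genes called higher the ratio was 0.415 (0.305 to 0.778), also below the 0.961 to 1.07 of 3 simulated pairs with equal responses, but an equal response stays open, since the highest ratio came near 0.8, as few as 7 genes were called, and simulated settings exclude nothing by themselves. A weaker response of the falling genes in the resistant line is only a hypothesis, since a preparation batch of the TN09-16 mock libraries could raise the TN09-16 changes in the same way and stays open (outside the range of the other 9 libraries on 0 of 4 library measures).

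Of the 191 genes lower on infection in TN09-16, 61 were also called lower in mock TN09-29 than in mock TN09-16, where 1.15 are expected of independent lists. Simulated unchanged groups sharing the mock libraries had 0, but made a mean of 0.5 calls for infection in TN09-16, too few to show how many of the real calls the sharing would place in both. The log2 fold changes of the comparisons had a correlation of 0.493 (simulated 0.479) and a covariance of 0.104 (simulated 0.0461). With each TN09-16 mock library left out of the calling in turn, the median of mock TN09-29 over that library lay at -0.697, -0.923 and -0.948 relative to all genes, which argues against chance values of single libraries as the whole source. With 3 mock libraries the controls could not be split into parts of 2, so part of the excess may come from the sharing, and a preparation batch of these libraries cannot be told apart from the group, although they lay outside the range of the other 9 on 0 of 4 library measures.

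Line differences lay close together along the chromosomes. Of 73 called genes, 16 had another within 10 tested genes, against a median of 4 in 10000 random sets (permutation p = 2e-04). This argues against random placement of genes taken singly. Neighbouring genes that change together for any reason would also give this, and no other gene list was tested for comparison. On chromosome 7, 10 consecutive tested genes from Glyma.07G195900 to Glyma.07G197200 averaged 1.82-fold the TN09-16 level in TN09-29, a value raised by picking the largest of 29295 windows on the same libraries. Of the 10, 8 passed the threshold in the contrast averaged over treatments, and 3 were called in both line comparisons. This run led 6 past the 95th percentile of shuffles. A run on chromosome 6 (median -0.82) and 1 on chromosome 5 (median -0.77) were also reached by 0 of 1000 shuffles. For the run on chromosome 7, 0 of 1000 shuffles of gene positions had a run with as large a median (permutation p = 0.001, the smallest they can give). Reads of TN09-16 failing to map could give such a run and stay open. The between-gene SD of the 10 changes was 0.0988 (95% limits 0 to 0.327) with genes taken as independent. This allows loss by a nearly equal factor, under a bound changed after the value was seen. The 10 tested genes on either side had medians of 0.04 and -0.08. Over all chromosomes, 90% of neighbouring called pairs changed in the same direction (62.8% by chance, exact binomial p = 0.103, pairs taken as independent). These pairs include runs lower in TN09-29, as on chromosome 18. The share leaves reads of 1 line failing to map open for neighbouring genes and does not bear on the chromosome 7 run alone. Segments that differ between the lines are a hypothesis that was not tested on sequence, and Glyma.07G195900, known from the literature as the NSF gene RAN07 although the files do not pair ID and name, was singled out after its value was seen (0.88 on the log2 scale, SE 0.13).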
